A study of Mus musculus with 28 samples.

How the data were processed

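Libraries of 28 single metaphase II oocytes of C57BL/6 mice, 14 WT and 14 KO by the genotype in the labels, were made by bisulfite treatment of the lysed cell and random-primed synthesis of both strands, per the labels' protocols. Reads were trimmed with Trim Galore 0.3.7 and aligned and called with Bismark 0.13.1 and Bowtie2 to the mouse build NCBIM37, per the submitters' processing notes. The version of Bowtie2 and whether duplicate reads were removed are not given in the sources used here. Each oocyte had 2 deposited files, 1 for each read of the pair, that give counts of methylated and of unmethylated calls at each covered CpG cytosine. The deposited files also give the percent of methylated calls, which was recomputed from the counts for every cytosine and used no further. Calls of both reads were summed per cytosine, so a fragment whose reads overlap adds a call from each at a shared cytosine, and copies made by PCR are not told apart. Intervals on pooled calls are exact Clopper-Pearson 95% intervals that take calls as independent. They leave out these repeated calls and the spread between oocytes, and are therefore too narrow. The number of covered cytosines limits the precision of a region more than that of an oocyte: with 1.37 to 1.64 calls per covered cytosine, a single cytosine gives little more than a yes or no per oocyte.

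The level of an oocyte is the mean over its covered autosomal CpG cytosines (chromosomes 1 to 19, at least 1 call) of the methylated share of calls. The same value was computed for the X chromosome and, as an upper bound on unconverted cytosines, for mitochondrial DNA, where it was 1.67% ± 0.442 (SD, n = 14) in WT and 1.67% ± 0.412 (SD, n = 14) in KO. CpG-dense bins are 1-kb autosomal bins in which at least 80 distinct CpG cytosines were seen over all oocytes, and CpG-poor bins had fewer than 20. Autosomal 10-kb tiles were classed as high (above 80%), middle (20 to 80%) or low (below 20%) by the even-numbered WT oocytes, as the mean of at least 3 oocytes with at least 5 covered cytosines each, and compared in the oocytes that did not class them. The share of intermediate tiles counts, among the tiles of an oocyte with at least 10 covered cytosines, those at 20 to 80%. An oocyte entered the mean of a tile or bin with at least 5 covered cytosines there. Tiles were compared with at least 7 oocytes in each genotype, bins with at least 5, and even- or odd-numbered oocytes alone with at least 3. Windows of 1 kb count as covered in 1 genotype and absent from the other with at least 20 observations of cytosines, summed over oocytes, in the former and 0 in the latter.

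Group labels were taken from the titles and the genotype. The labels name no animal, so each genotype is 1 sample, and oocytes of a group may share a mother. No p-value, standard error or interval between genotypes is given, and differences are described by the means, the SD between oocytes and the overlap of the oocytes. The design set before the data were examined named permutation tests over oocytes, quasi-binomial logistic models per region and limma as an alternative. These had been run with oocytes as replicates, together with regroupings of the oocytes, before the tests were set aside for this reason, and none of them is reported. In their place, regions were counted by the size of the difference of group means. The size of 20 points, the larger size of 40 points, the comparison of even with odd oocyte numbers within a genotype, the CpG-dense bins above 80%, the density classes and the runs of tiles were chosen after the data were seen. The size of 10 points was planned. Calls were simulated for the 170266 tiles at the depth of these oocytes, without spread between oocytes of a genotype. Covered cytosines were drawn independently, which leaves out any correlation between nearby cytosines. The changed tiles were taken among those with an intermediate level over all oocytes. Of the unchanged tiles, 283 (0.166%) passed 20 points, as did 8% of tiles changed by 10 points and 100% of tiles changed by 40 points. For the 17590 CpG-dense bins the simulation gave 0 unchanged bins, 0% and 100%. The changed bins had a low level over all oocytes and were changed upward only, so decreases from high levels were not simulated for bins. All these shares cover counting error only, with cytosines taken as independent. The comparisons of even with odd oocyte numbers, which hold the real spread but fewer oocytes, gave larger shares.

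The named regions are the 10 tiles with the largest decrease and the 10 with the largest increase, and the 5 CpG-dense bins each way, at most 1 per Mb. The rule as first set took them among regions past a test, a condition that was dropped with the tests. WT oocyte 1 and the oocyte numbers 6, 7, 14 and 15 stood apart after the data were seen, and values without the former, planned only for the autosomal level and its spread, and within the latter were added. Alternatives were each read alone, at least 2 calls per cytosine, calls counted once each, thinning of all oocytes to 2181154 autosomal cytosines, cytosines with more than 10 calls left out, other minimums of covered cytosines, 100-kb tiles, at least 120 cytosines per bin, and the genome-wide level as an offset. Gene bodies, promoters, gene lists and the place of Hira were not analysed here: the gene table used for names is on GRCm38.p6, another build, and no coordinates were converted. Values were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.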

Results

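CpG methylation was measured by single-cell bisulfite sequencing in 28 single mouse oocytes at metaphase II, the stage at which the mature egg waits for fertilisation. The 14 WT oocytes carried floxed Hira alleles without Cre. The 14 KO oocytes carried in addition Gdf9-iCre, a Cre recombinase driven from the regulatory sequence of Gdf9, a gene of the growing oocyte. Hira encodes a histone chaperone that deposits a variant of histone H3 on DNA outside replication. Mouse oocytes acquire most of their DNA methylation while they grow, and the comparison asks how far the oocyte methylome forms when Hira has been deleted. The labels name no female for any oocyte, so the oocytes of a genotype count as 1 sample, and no test between genotypes was possible. Each value is a mean over oocytes with the SD between oocytes and the number of oocytes as n. An oocyte covered between 2181154 and 6383732 autosomal CpG cytosines, with 3066652 to 10594561 methylation calls in all and 1.37 to 1.64 calls per covered cytosine.

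KO oocytes had a lower methylation level than WT oocytes on the autosomes and on the X chromosome. The mean autosomal level was 30.7% ± 3.27 (SD, n = 14) in WT and 18.0% ± 3.65 (SD, n = 14) in KO, a difference of -12.7 percentage points. WT oocytes lay between 27.4% and 40.7% and KO oocytes between 12.2% and 23.3%, so all 14 KO oocytes lay below the lowest WT oocyte. Of the pooled calls, 22152990 of 77519717 were methylated in WT (28.6%, exact Clopper-Pearson 95% interval 28.57 to 28.59%) and 16234820 of 94439875 in KO (17.2%, 17.18 to 17.20%). These intervals take calls as independent and leave out the spread between oocytes, so they are too narrow. The X chromosome level was 33.2% ± 4.80 (SD, n = 14) in WT and 19.4% ± 3.32 (SD, n = 14) in KO. WT oocyte 1 stood apart at 40.7%, and without it the autosomal WT level was 29.9% ± 1.61 (SD, n = 13). Libraries with the oocyte numbers 6, 7, 14 and 15 held a larger share of their cytosines in CpG-dense sequence in both genotypes, 18.7 to 22.6% against 12.3 to 18.6% in the others. Within these numbers the autosomal level was 27.7% ± 0.285 in WT and 15.7% ± 3.15 in KO (SD, n = 4 each), and among all other numbers it was 31.8% ± 3.15 and 18.9% ± 3.53 (SD, n = 10 each).

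**Figure D1:**
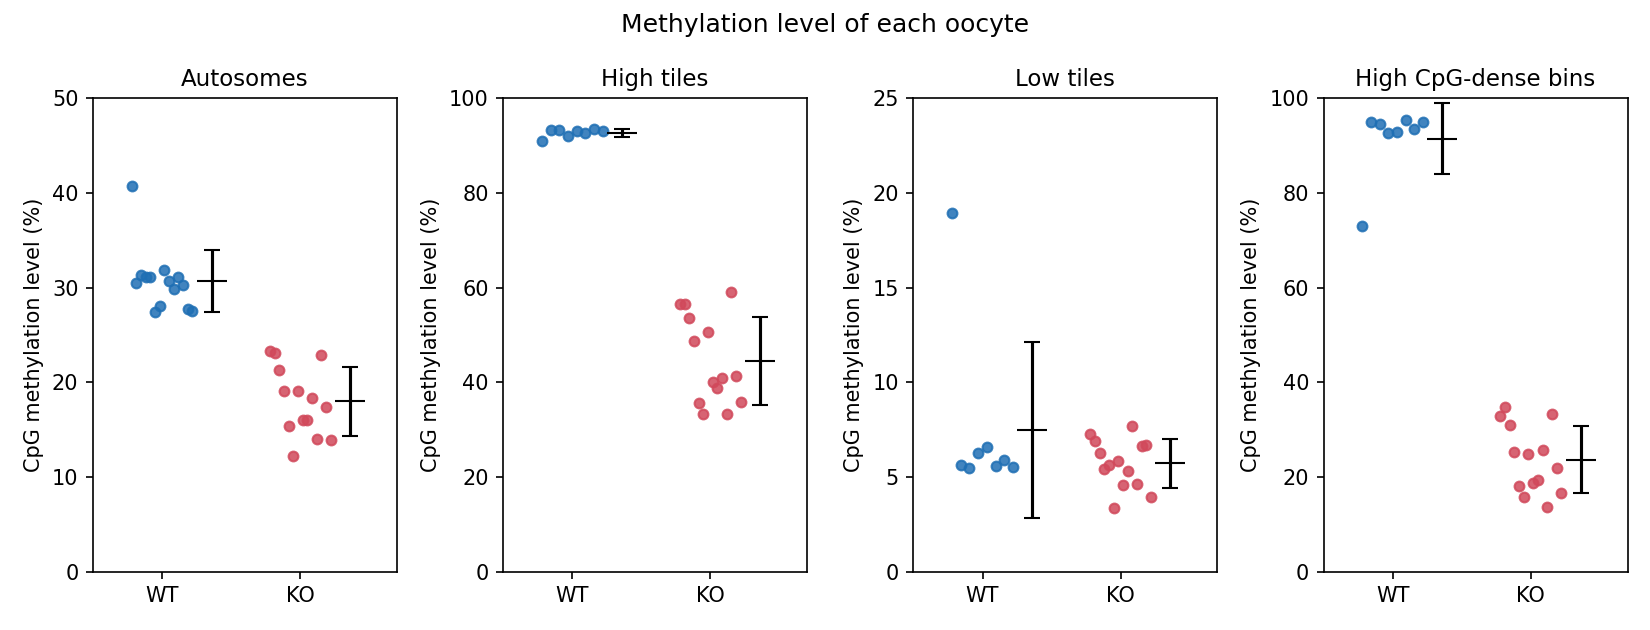
CpG methylation level of each oocyte (percent, vertical axes, whose ranges differ) by genotype on the autosomes, in high tiles, in low tiles and in high CpG-dense bins; each point is 1 oocyte, and the black lines give the mean and SD. The autosomal level of KO oocytes ends at 23.3% where that of WT oocytes starts at 27.4%, while in low tiles the genotypes overlap and WT oocyte 1 lies at 18.9%.

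The difference lay in regions that are methylated in WT oocytes, at high or intermediate levels. The oocyte methylome consists of long methylated domains, most of them over transcribed units, between domains with little methylation. Autosomal 10-kb tiles were classed by the level of the 6 even-numbered WT oocytes, and the level was then compared in the 8 odd-numbered WT oocytes and the 14 KO oocytes. In the 39420 high tiles (above 80%) the level was 92.7% ± 0.868 (SD, n = 8) in WT and 44.6% ± 9.27 (SD, n = 14) in KO, where oocytes ranged from 33.3% to 59.0%. In the 46447 middle tiles (20 to 80%) it was 43.6% ± 3.18 (SD, n = 8) in WT and 21.8% ± 4.49 (SD, n = 14) in KO. In both classes all 14 KO oocytes lay below the lowest WT oocyte. In the 91044 low tiles (below 20%) the level was 7.49% ± 4.63 (SD, n = 8) in WT and 5.73% ± 1.28 (SD, n = 14) in KO. Without WT oocyte 1, at 18.9%, the WT level in low tiles was 5.86% ± 0.415 (SD, n = 7), and the remaining difference of -0.128 points was smaller than either SD. With tiles classed by the odd-numbered WT oocytes instead, low tiles were at 5.37% in WT and 5.55% in KO.

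The high tiles of KO oocytes were mostly at intermediate levels. Of the high tiles measured in an oocyte, 90.3% ± 1.17 (SD, n = 8) were above 80% in WT and 6.91% ± 7.47 (SD, n = 14) in KO, where single oocytes ranged from 0.853% to 22.4%. Another 77.7% ± 4.87 lay between 20 and 80% in KO, against 9.59% ± 1.12 in WT, and 15.4% ± 6.66 lay below 20% in KO, against 0.153% ± 0.139 in WT. Over all autosomal tiles, the share at 20 to 80% was 25.2% ± 7.36 (SD, n = 14) in WT and 35.7% ± 3.61 (SD, n = 14) in KO. WT oocyte 1 alone was at 50.4%, and without it WT was at 23.2% ± 1.26 (SD, n = 13), with all 14 KO oocytes above the highest WT oocyte. The lower level in high tiles was spread over the autosomes, on each of which the KO mean lay between 42.8% and 47.3% and the WT mean between 91.5% and 93.3%. Within oocyte numbers 6, 7, 14 and 15, high tiles were at 92.6% in WT (n = 2) and 40.3% in KO (n = 4), and among the other numbers at 92.7% (n = 6) and 46.3% (n = 10).

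CpG-dense sequence that WT oocytes methylate showed a larger difference than CpG-poor sequence. CpG-dense 1-kb bins, used in place of CpG islands, are mostly unmethylated in oocytes, and over all of them the level was 3.51% ± 0.328 (SD, n = 14) in WT and 2.39% ± 0.490 (SD, n = 14) in KO, with 12 of 14 KO oocytes below the lowest WT oocyte. This difference of -1.12 points was -0.526 points with at least 2 calls per cytosine and -0.435 points in bins with at least 120 cytosines. In the 637 CpG-dense bins above 80% in the even-numbered WT oocytes, the level was 91.5% ± 7.49 (SD, n = 8) in odd-numbered WT oocytes and 23.7% ± 7.07 (SD, n = 14) in KO. WT oocyte 1 was at 73.1% there, and the other odd-numbered WT oocytes were at 94.1% ± 1.12 (SD, n = 7). CpG-poor bins were at 37.8% ± 3.57 (SD, n = 14) in WT and 22.8% ± 3.93 (SD, n = 14) in KO. Within the high tiles, the KO level was 49.4% ± 8.84 (SD, n = 14) in the sparsest bins, with under 10 cytosines, and 16.4% ± 6.17 (SD, n = 14) in the densest, with at least 120. The WT levels were 90.0% ± 0.621 and 87.6% ± 12.8 (SD, n = 8), the latter 92.0% ± 2.86 without WT oocyte 1 (SD, n = 7). Relative to WT, the KO level was 54.9% in the sparsest bins and 18.7% in the densest. The difference in high CpG-dense bins was -73.9 points within oocyte numbers 6, 7, 14 and 15 and -65.4 points among the other numbers.

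**Figure D2:**
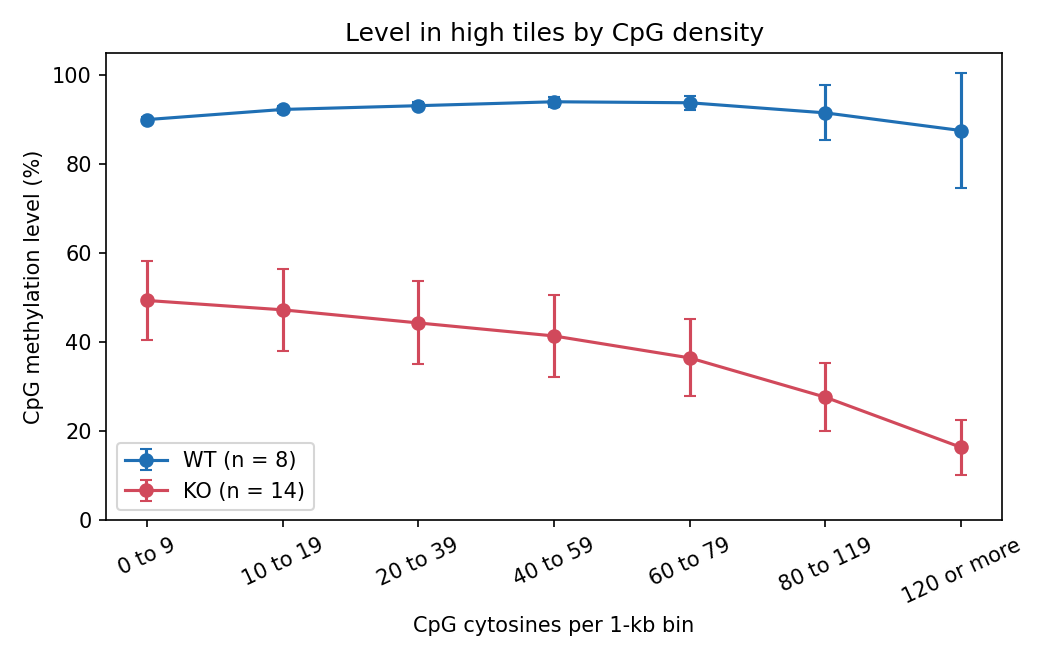
CpG methylation level (percent, vertical axis) in high tiles of odd-numbered WT oocytes (n = 8) and KO oocytes (n = 14), by the number of CpG cytosines in a 1-kb bin (horizontal axis); points are means over oocytes and bars are the SD. The KO mean is 49.4% in the sparsest bins and 16.4% in the densest, where the WT mean is 87.6%.

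The spread of the autosomal level between oocytes was larger in KO, while that of the X chromosome level had no fixed direction. The mean absolute deviation of the autosomal level from the group median was 1.90 points in WT and 3.02 points in KO, a difference of 1.11 points. WT oocyte 1 made up much of the WT value, which was 1.26 points without it, a difference of 1.75 points. The difference was 2.38 points within oocyte numbers 6, 7, 14 and 15, 1.61 points among the other numbers, and 0.626 points with at least 2 calls per cytosine. The SD of the X chromosome level was 4.80 points in WT, or 3.56 points without WT oocyte 1, and 3.32 points in KO, but 2.68 points in WT and 3.70 points in KO within oocyte numbers 6, 7, 14 and 15 (n = 4 each).

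Tile by tile, a lower KO level was far more frequent than a higher one. Of 170266 autosomal 10-kb tiles measured in at least 7 oocytes of each genotype, 59869 (35.2%) had a KO mean at least 20 points below the WT mean and 3829 (2.25%) a KO mean at least 20 points above it. Even against odd oocyte numbers of the same genotype gave 3.00% and 1.53% in WT and 2.55% and 1.22% in KO, with 6 oocytes on 1 side and 8 on the other. Without WT oocyte 1 the WT shares were 2.34% and 2.09%. Again with 6 and 8 oocytes, between the even-numbered KO and the odd-numbered WT oocytes the shares were 37.5% and 2.41%, and between the odd-numbered KO and the even-numbered WT oocytes 33.6% and 3.26%. Of 17590 CpG-dense bins, 1024 were at least 20 points lower and 48 at least 20 points higher in KO, against 54 and 81 of 17344 between even- and odd-numbered WT oocytes (82 and 64 of 17280 without WT oocyte 1) and 39 and 13 of 17561 between even- and odd-numbered KO oocytes. By class, with the odd-numbered WT oocytes alone against KO, 36661 of 38422 high tiles (95.4%) were at least 20 points lower in KO. Of the middle tiles, 22383 of 44940 were lower and 1130 higher, and of the low tiles 2391 of 88313 were lower and 2679 higher (1511 and 3216 without WT oocyte 1). Within oocyte numbers 6, 7, 14 and 15, 36523 tiles were lower and 2508 higher of 104237, and among the other numbers 51224 were lower and 3358 higher of 143728.

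Regions picked in even-numbered oocytes mostly differed in the same direction in odd-numbered ones. The 60139 tiles at least 20 points lower in the even-numbered KO than in the even-numbered WT oocytes were at 73.7% ± 1.82 in the odd-numbered WT and 35.0% ± 7.24 in the odd-numbered KO oocytes (SD, n = 8 each). Of the 58764 measured there, 98.6% were lower by any amount and 86.7% by at least 20 points. A lower KO level was common over all tiles, but in low tiles this depended on WT oocyte 1. The third quartile of the difference over all tiles was -1.70 points for even-numbered KO minus odd-numbered WT oocytes, which include WT oocyte 1. It was 1.36 points for odd-numbered KO minus even-numbered WT oocytes, which do not include it. In low tiles the median difference of all KO minus odd-numbered WT oocytes was -2.54 points, but 0 without WT oocyte 1. The 5188 tiles at least 20 points higher were at 17.2% ± 5.95 in WT and 38.8% ± 8.16 in KO (SD, n = 8 each). Of 4954 measured, 86.1% were higher by any amount and 48.5% by at least 20 points. Without WT oocyte 1 the WT level in these tiles was 15.2% ± 1.00 (SD, n = 7), with 89.6% higher by any amount and 55.8% by at least 20 points. The 955 CpG-dense bins picked as lower were at 67.1% ± 6.34 in WT and 17.9% ± 4.93 in KO. Of 946 measured, 940 were lower by any amount, and 88.7% by at least 20 points. The 55 bins picked as higher were at 6.84% ± 1.31 in WT and 32.6% ± 9.30 in KO. Of these, 51 were higher by any amount, and 58.2% by at least 20 points.

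The 10 tiles with the largest decrease from WT to KO had WT means of 95.3 to 99.4% and KO means of 1.59 to 5.31%. In each of them the oocytes of the genotypes did not overlap. All named regions were picked for their difference in these same oocytes. Their differences are therefore likely to be overstated, the lack of overlap partly follows from the choice, and intervals given for them leave the choice out. The first, on chromosome 1 from 162770001 to 162780000 (coordinates of build NCBIM37 throughout), was at 97.5% ± 5.28 (SD, n = 11) in WT and 2.30% ± 3.56 (SD, n = 14) in KO. The calls there were 192 methylated of 196 in WT and 11 of 319 in KO. The deepest of the 10, on chromosome 4 from 133040001 to 133050000 with 2463 covered cytosines summed over oocytes, was at 97.7% ± 2.40 (SD, n = 13) in WT and 5.04% ± 2.56 (SD, n = 14) in KO. The others started at 38420001 and 132340001 on chromosome 1, 122310001 and 126130001 on chromosome 8, 18310001 on chromosome 10, 11300001 on chromosome 12, 55810001 on chromosome 16 and 68430001 on chromosome 18. The CpG-dense bin with the largest decrease, on chromosome 15 from 88980001 to 88981000, was at 99.5% ± 1.56 (SD, n = 9) in WT and at 0 in all 10 KO oocytes measured. There 0 of 255 calls were methylated, which allows a level of up to 1.44% if calls are independent (exact Clopper-Pearson 95% bound). The other 4 bins started at 37482001 on chromosome 5, 98635001 on chromosome 11, and 149072001 and 150253001 on chromosome 4. Which genes these regions hold was not analysed here.

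The 10 tiles with the largest increase had WT means of 1.90 to 15.2% and KO means of 65.6 to 80.8%, on 142 to 430 covered cytosines each, and in 6 of them the genotypes did not overlap. The first, on chromosome 11 from 34500001 to 34510000, was at 5.45% ± 8.90 (SD, n = 13) in WT, or 3.27% without WT oocyte 1, and at 72.4% ± 11.9 (SD, n = 12) in KO. In it, 16 of 288 calls were methylated in WT (5.56%, 3.21 to 8.87%) and 172 of 242 in KO (71.1%, 64.9 to 76.7%). The second, on chromosome 18 from 56440001 to 56450000, was at 15.1% ± 13.1 (SD, n = 11) in WT and 80.8% ± 15.7 (SD, n = 13) in KO. Without WT oocyte 1 the WT mean was 0 instead of 1.90% in the tile at 28680001 on chromosome 12, 0.909% instead of 3.56% at 5880001 on chromosome 18 and 1.11% instead of 3.74% at 161700001 on chromosome 1. The others of the 10 started at 136020001 on chromosome 6, 114830001 on chromosome 8, 73800001 on chromosome 9, and 11210001 and 110960001 on chromosome 13. Among CpG-dense bins the largest increase was on chromosome 18 from 74090001 to 74091000, at 0.948% ± 1.49 (SD, n = 11) in WT and 64.5% ± 25.5 (SD, n = 12) in KO. The next bins were on chromosome 17 from 34808001 (6.16% to 59.4%), chromosome 7 from 28114001 (4.68% to 56.8%), chromosome 1 from 43089001 (1.17% to 46.9%) and chromosome 19 from 60543001 (1.40% to 46.9%). The genotypes did not overlap in 2 of these 5 bins. These tiles and bins too were picked for their difference in the same oocytes, so their differences are likely to be overstated.

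Tiles with a higher KO level often lay side by side. Of the 3829 tiles, 1440 (37.6%) lay in runs of at least 3 adjacent tiles, while as many tiles drawn at random from those measured gave at most 21 in any of 100 draws. The draws ignored the long domains of the oocyte methylome and the tile class, although 0 of the 3829 were high, 835 middle and 2822 low tiles. They therefore cannot show whether such runs exceed what these domains alone would give. The longest run, on chromosome 4 from 95290001 to 95470000, was at 9.57% ± 6.39 (SD, n = 14) in WT and 50.0% ± 14.3 (SD, n = 14) in KO, with all 14 KO oocytes above the highest WT oocyte. The tiles on either side of it were also higher in KO, but were measured in fewer than 7 WT oocytes. A run as long on chromosome 9, from 101820001 to 102000000, was at 16.3% ± 8.78 in WT and 52.4% ± 13.2 in KO, with 13 of 14 KO oocytes above the highest WT oocyte.

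**Figure D3:**
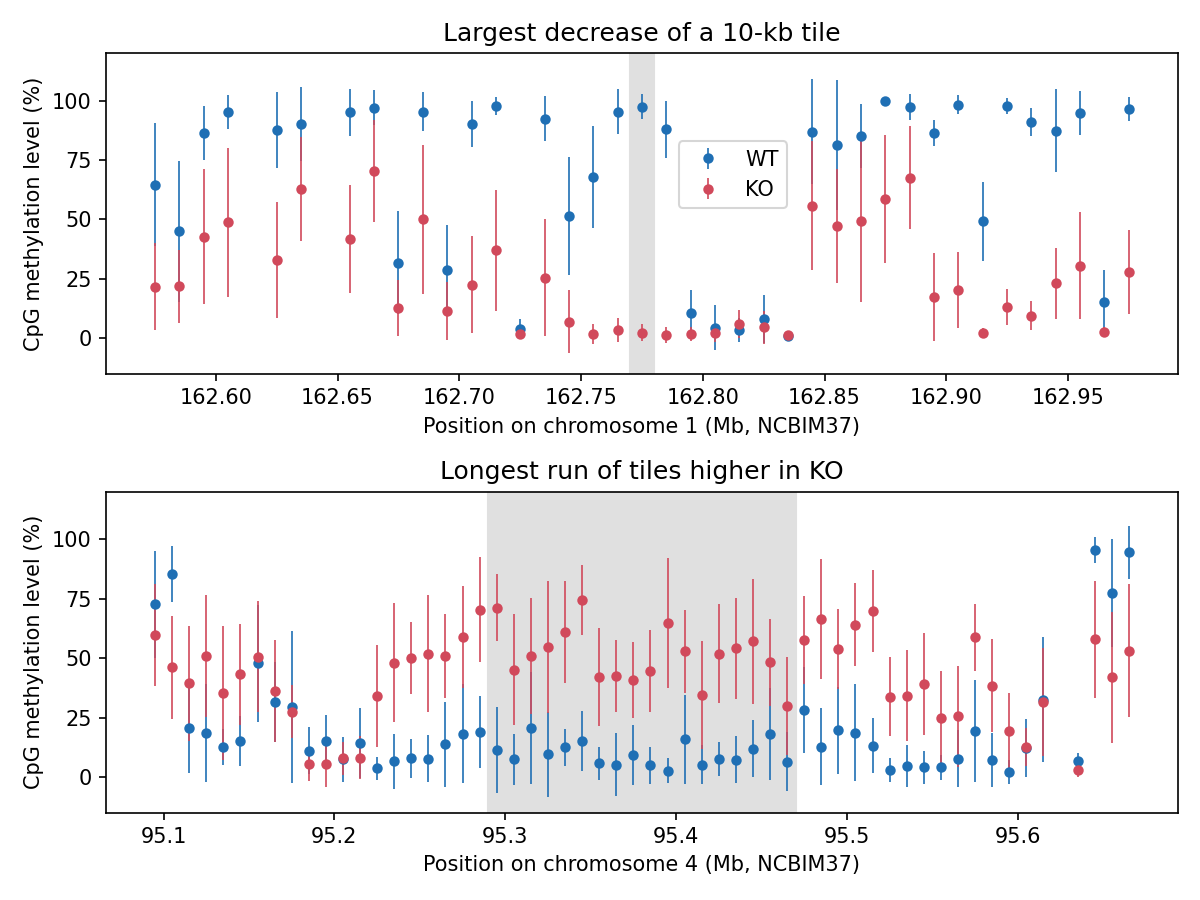
CpG methylation level (percent, vertical axes) of 10-kb tiles along chromosome 1 around the tile with the largest decrease and along chromosome 4 around the longest run of tiles with a higher KO level (horizontal axes, position in Mb); points are means over the oocytes of a genotype, bars are the SD and the grey areas mark the tile and the run. In the grey tile WT is at 97.5% and KO at 2.30%, and in the grey run WT is at 9.57% and KO at 50.0%.

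The deleted part of Hira was not examined, because no gene annotation of the build was used here. Of 2410872 1-kb windows, 80 were covered in WT, with at least 20 observations of cytosines, and absent from KO, 2 of them on chromosome 16, the chromosome of Hira. Another 335 were covered in KO and absent from WT, 13 of them on chromosome 16. The 2 counts rest on unequal coverage, as WT held 45.7% and KO 54.3% of all observations. Whether any of the windows on chromosome 16 lies in Hira was not examined. Without WT oocyte 1, 608 windows were absent from WT.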

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

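All tests of the lower KO level and of WT oocyte 1 were chosen after those results were seen. For chromosome 4 the expected outcomes were written before the tests, but the stretch itself had been found in these data. Cytosines of the Y chromosome were outside every comparison, and each oocyte listed some, with a median of 93 (42 to 147), above the limit of 3 that a count of 0 allows.

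Of the technical explanations for the lower KO level, less complete bisulfite conversion in WT would raise its mitochondrial level, which differed between the genotypes by 0.00295 points. Conversion of methylated cytosines in KO would lower sparse and dense sequence alike, but in high tiles the KO level as a percent of the WT level differed by -36.2 points between the densest and the sparsest bins. These bins lie partly in different tiles. Within the same high tile the gap was smaller, with KO at 29.4% of the WT level at CpG-dense and 44.0% at CpG-poor cytosines. An equal loss in all sequence would also leave high tiles close to each other in KO. Their WT means ran from 81.1% at the 5th to 98.3% at the 95th percentile. The KO means ran from 14.8% to 69.6%, with a Pearson r of 0.895 across tiles between even- and odd-numbered KO oocytes. A different share of CpG-dense cytosines between libraries would act less with every 10-kb tile counted once, where the difference was -14.3 points, and the smaller share in KO (16.7% against 17.6% in WT) would raise the KO level, since dense bins carry little methylation. These values argue against each of them as the whole cause, for conversion in KO as a loss that is equal in all sequence. A loss in conversion that depends on the sequence was not tested. An effect of the Hira deletion stays open as a hypothesis, found and tested on the same data. Differences between mothers or collection days remain open and untested, since the labels name neither.

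WT oocyte 1 had the highest autosomal level, 40.7%, and a level of 90.8% in high tiles, below the 92.0 to 93.4% of the other odd-numbered WT oocytes. Incomplete conversion would raise its mitochondrial level above the others, but this was 1.33% and the highest other WT oocyte had 2.57%. DNA of a second oocyte would leave low tiles at the level of other oocytes, but these were at 18.9%, against 5.50 to 6.58% in the other odd-numbered WT oocytes. DNA of cells that are not oocytes may have been present: its median low tile was at 19.7%, against at most 3.64% in the other WT oocytes, so most low tiles were raised, and its calls at cytosines covered more than once were mixed in 10.3% of cases, against at most 3.78%. No other source was tested, and nothing shows which cells these were.

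Windows covered in WT and absent from KO were dense on chromosome 4, where 17 of the 80 lay between 20004001 and 33800000, the most within 15 Mb. None of the 335 reverse windows lay there. Of these, at most 15 lay within 15 Mb, on chromosome 12 from 91806001 to 105197000. Most of these chromosome 12 windows lay between 105032001 and 105197000. Other reverse windows lay closer still, as between 116604001 and 116627000 on chromosome 11. Clusters as such were therefore not particular to chromosome 4. These reverse clusters were far shorter, however, while the chromosome 4 windows were scattered along the whole stretch, so the 2 kinds are not alike. Poor coverage of the whole stretch in KO is argued against by the KO share of observations outside the absent windows, 52.9%, against 54.4% genome-wide. A different haplotype of the KO oocytes there could leave more cytosines without any KO coverage, and outside the absent windows the share of cytosines covered in at least 6 WT oocytes that no KO oocyte covered was 4.63 times that of the genome, above the value of 2 set beforehand for this explanation, while the reverse share was 1.02 times that of the genome. With at least 4 WT oocytes, a setting that had been run first although at least 6 was the planned one, the ratios were 1.97, just short of that value, and 1.14. The haplotype therefore stays open, as the stretch was also picked for its absent windows.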

How the results depend on the processing

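The direction turned in 1 case: with tiles classed by odd-numbered WT oocytes, low tiles were 0.174 points higher in KO (5.37% in WT, 5.55% in KO), a difference below the SD between oocytes as before. Of 140 alternative values of the main results, 114 stayed within 1 SD of the value reported or, for counts, within 1.5 times, and 26 moved further. Among the 140 were 56 that left out 1 oocyte. All 56 stayed within 1 SD, but leaving out 1 of 14 oocytes can hardly move a mean that far. The 26 all came from the other alternatives. Alternatives at 40 points, within oocyte numbers and, except for the autosomal level and its spread, without WT oocyte 1 were chosen after the data were seen. Leaving out each oocyte in turn gave autosomal differences of -13.1 to -11.9 points and differences in spread of 0.871 to 1.75 points. With at least 2 calls per cytosine the difference in spread was 0.626 points. Without WT oocyte 1, the named regions that were measured in it stayed within 1 SD. The CpG-dense level differed by -0.526 points with at least 2 calls per cytosine and by -0.435 points with at least 120 cytosines per bin; the cause was not tested. At 10 points, 9050 tiles and 123 CpG-dense bins were higher in KO, and at 40 points 31003 tiles differed, 30462 lower and 541 higher, with 13 bins higher. In some settings fewer regions were measured. With at least 10 covered cytosines per oocyte, 38878 of 105902 tiles differed by at least 20 points (36832 lower and 2046 higher). Of 23882 tiles of 100 kb, 6134 differed (6003 lower and 131 higher). With at least 120 cytosines per bin, 239 of 8989 bins differed (226 lower and 13 higher). Within oocyte numbers 6, 7, 14 and 15, 39031 of 104237 tiles (36523 lower and 2508 higher) and 638 of 14740 bins (600 lower) differed. The share that was lower also fell in 100-kb tiles, to 25.1% from 35.2%. In bins it fell from 5.82% to 2.51% with at least 120 cytosines and to 4.07% within those numbers. With the genome-wide level as an offset, 7692 tiles were higher and 44373 (26.1%) lower in KO, since the offset takes the genome-wide decrease out. Lower tiles were then 85.2% of the tiles past 20 points, against 94.0% in the main result. At least 30 observations left 21 windows absent from KO and 86 absent from WT, and without WT oocyte 1, which covers many cytosines, 608 were absent from WT. No paired analysis was possible because no result comes from a test, and for values over all 28 oocytes a block would leave the difference of means as it is, since both genotypes hold the same 14 numbers. The deviations of tile levels from the group means were not correlated between oocytes of the same number (mean r = -0.0167, and 1 of 28 oocytes correlated best with its own number), although the mean level of numbers 6, 7, 14 and 15 was lower than that of the others in both genotypes. Gene bodies, promoters, gene lists, limma and the fits with a replicate block are not reported, the first 3 for want of an annotation of the build and the others because they are tests over oocytes. In the simulation, at the depth of these oocytes, the difference of a single tile had an error of 5.79 points (SD over the 200 changed tiles). This covers counting error only, with cytosines taken as independent, and the spread between oocytes comes on top of it. The changed tiles had intermediate levels, and no change was simulated in other tiles. At intermediate levels, differences of single tiles below this size are therefore not resolved, and larger ones may not be either.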

Other observations

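The values in this part were all looked for after the main results were seen. Over 25288 high tiles measured in at least 4 oocytes on each side, the means of the even-numbered and of the odd-numbered KO oocytes correlated with a Pearson r of 0.895 and a Spearman rho of 0.881, across tiles, which are not independent replicates. In WT they were 0.689 and 0.612 over 17369 high tiles, but the even-numbered WT oocytes had classed these tiles and WT levels there lie in a narrow range, so the values cannot be compared between the genotypes. The KO mean of a high tile ran from 14.8% at the 5th percentile over 48.7% at the median to 69.6% at the 95th percentile. High tiles without a high neighbour were at 39.3% ± 8.09 in KO and 89.8% ± 0.934 in WT, and those in runs of at least 10 were at 50.0% ± 10.4 and 94.5% ± 1.06 (SD, n = 14 KO and 8 WT). Within the same high tile, CpG-dense minus CpG-poor cytosines gave -12.6 points ± 3.15 (SD, n = 14) in KO and 1.60 points ± 6.91 (SD, n = 8) in WT, or 3.96 ± 1.91 (SD, n = 7) without WT oocyte 1.

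Further runs of tiles with a higher KO level lay on chromosome 6 from 135950001 to 136120000 (8.91% ± 6.89 in WT, 44.0% ± 13.2 in KO) and on chromosome 18 from 56150001 to 56300000 (11.1% ± 4.21 in WT, 43.2% ± 12.3 in KO, SD, n = 14 each). In the latter all 14 KO oocytes lay above the highest WT oocyte. On the X chromosome, the 1-kb window from 47014001 to 47015000 held 253 observations of cytosines in 11 WT oocytes and 0 in KO oocytes. In the reverse direction, 10 windows between 116604001 and 116627000 on chromosome 11 were covered in 10 to 14 KO oocytes each and in 0 WT oocytes.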
